A study of Homo sapiens with 3 samples.

How the data were processed

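Gene expression was measured on 3 2-colour Agilent whole human genome arrays, 1 for each of 3 sets. Per the labels, siRNA or a control oligo was delivered to MDA-MB-231 cultures that had reached 80% confluency. The study's design text calls the control a mock transfection instead, so what the control cells received is not settled here. RNA was taken after 48 h per the labels, and 200 ng was labelled, with the siRNA sample in Cy3 and the control in Cy5. The labels state duplicate experiments for each set but do not say whether the sets used the same siRNA, came from separate cultures or shared a control RNA. The p-values therefore measure only the spread between these arrays, which may be technical, and if the control RNA was common they leave out the control's own spread. The arrays were on the same slide, so no batch could be tested.

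The deposited scanner files hold an intensity for each spot and channel (median pixel signal, background and processed signal). Agilent Feature Extraction 9 made them per the submitters' processing notes, and version 9.5.3.1 per the file headers. The deposited log10 ratio of each spot is that of processed Cy5 over Cy3, per the file headers. The authors' deposited table gives 1 mean log10 ratio for each of 22450 transcript accessions. For 95.9% of 11315 accessions with 1 probe, it equals the mean over the arrays of the sign-turned log10 ratio within 1e-04, so its direction is siRNA over control. How the authors combined several probes is not given in the sources used here.

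Each array held 45015 spots, of which 1639 were controls and 43376 carried 41000 gene probes. Median signals were background-corrected (normexp, offset 50) and normalised by loess within each array in limma 3.58.1 (R 4.3.3), with control and outlier spots at weight 0 and left out afterwards. Outlier spots numbered 333, 180 and 127, and saturated spots, which were kept, 5, 2 and 0. Ratios were turned to siRNA over control. Spots of a probe were averaged, and probes well above background in at least 1 channel on at least 2 arrays were kept. The brightest probe stood for a gene, and for many of the named genes the text gives other kept probes that turned sign or did not pass. Probes were named through a RefSeq table of assembly GRCh38.p14: 23434 by accession, 2317 by symbol and 1043 by older symbol, and 14206 kept the file's name. Of the names tested, 14048 matched the table. No coordinates are given, since the array was annotated on another build.

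The mean log2 ratio over the arrays was tested against 0 with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes tested, threshold 0.05). The named genes are HNRNPA2B1, the 12 largest falls and 12 largest rises among genes past the threshold with the same sign on every array, a signal at or above the median and a gene symbol, and in each list up to 4 members past the threshold with the largest change. For the lists the text gives examples of these genes. One gene among the largest rises and the sequence of the HNRNPA2B1 probe are not reported here. A gene named by several parts counts under each. The 20 lists (589 entries) were tested with camera (preset correlation 0.01), adjusted over the lists. They cover the hnRNP family, SR and other splicing factors, m6A and microRNA machinery, interferon response, NF-kappaB cytokines, G1/S and DNA replication, G2/M, histones, p53 targets, unfolded protein and integrated stress response, heat shock, cholesterol synthesis, hypoxia and glycolysis, mesenchymal and invasion genes, ribosomal proteins, oxidative phosphorylation, lysosome and autophagy, and luminal, leukocyte and fibroblast markers. Design, lists, naming rule and alternatives were fixed before the data were examined.

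The alternatives were no background correction, an offset of 16, the scanner software's processed signals, median centring, Aquantile between arrays, no or a stricter filter on dim probes, the mean of a gene's probes, outlier spots kept, eBayes with trend and robust settings, the channels fitted without the array, each array left out, other thresholds, and camera with an estimated correlation, on ranks, and fry. Regressing out the base composition of the probes was added after seeing the data.

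Comparison with random lists matched on signal went through 2 forms. The lists were first drawn within 50 bins of equal size, which gave a matched median of -0.17 for the ribosomal list. The brightest bin proved too wide, and the matching was changed, after that result was seen, to the 40 genes nearest in signal, which gave -0.36. The values in the text are from the second form unless stated.

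The steps were tested on simulated data for this comparison of 22335 genes with 200 changed. The fit recovered 27% of changes of 0.5 and 83% of changes of 1 on the log2 scale, with 2 unchanged genes called. These rates hold for 200 changed genes. They do not carry over to the data, where 9314 genes passed, since the adjustment depends on the share of genes changed. Raw Cy3 signals multiplied by known factors gave back 1.01 and -1.00 for shifts of 1 and -1 over 195 genes. A list of 30 genes shifted by -0.4 had camera adjusted p = 2.70e-05, with 0 of 19 other lists called.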

Results

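The study measured gene expression in MDA-MB-231 cells, an established human breast cancer line with mesenchymal features, after transfection of small interfering RNA (siRNA) against HNRNPA2B1. This gene encodes hnRNP A2/B1, an RNA-binding protein of the heterogeneous nuclear ribonucleoprotein (hnRNP) family that acts in splicing and RNA transport. Total RNA was taken 48 h after transfection, and 3 sets were hybridised, each on 1 array. Each array held the siRNA sample in Cy3 and, per the labels, a control oligonucleotide transfection in Cy5. The design text calls the control a mock transfection. The comparison asks which transcripts differ between knock-down and control-transfected cells. The median spot signal on arrays 1, 2 and 3 was 154, 214 and 178 in Cy3 and 312, 299 and 290 in Cy5, against background medians between 40 and 41. Between 70.2% and 73.7% of gene spots were well above background in Cy3, and the number of arrays limits the precision. No array had the dyes swapped, so dye and condition cannot be told apart in any ratio given here.

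HNRNPA2B1 mRNA fell in the siRNA channel of all 3 arrays. Its log2 ratio of siRNA over control was -1.21 ± 0.19 (SD, n = 3; limma, adjusted p = 2.28e-05), which left 43.2% of the control level. The arrays stood at 41.3%, 50.2% and 38.7% of control. The array holds 1 probe for this gene. The authors' deposited table gives a mean log10 ratio of -0.377, or 42.0% of control. HNRNPA2B1 ranked 17 among the falls of all genes tested.

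Several genes fell further than the target. AHR, the ligand-activated aryl hydrocarbon receptor, fell by 2.38 ± 0.17 on the log2 scale (SD, n = 3), and E2F8, an atypical repressor of the E2F family, fell by 2.09 ± 0.20. ITPR1, a calcium channel of the endoplasmic reticulum, fell by 1.74 ± 0.04, IMPA1, an inositol monophosphatase, fell by 1.67 ± 0.07, and the cytokine gene IL11 fell by 1.60 ± 0.14. RGS20, a regulator of G protein signalling, fell by 1.36 ± 0.05, and HSPA1A, an inducible HSP70 chaperone with a near-identical copy in HSPA1B, fell by 1.27 ± 0.16. The core splicing protein gene SNRPE fell by 1.25 ± 0.25, and HNRNPA1L2, whose sequence is close to that of HNRNPA1, fell by 1.25 ± 0.13. The ubiquitin-conjugating enzyme gene UBE2Z (fall of 1.21 ± 0.02) and ATP23 (fall of 1.18 ± 0.10) followed the target. Adjusted p lay between 4.29e-07 for AHR and 3.01e-05 for SNRPE (limma). The second IMPA1 probe read -1.56, whereas the second ATP23 probe read 0.03, the other HSPA1A probes -0.40 and -0.26 and the other UBE2Z probes -0.78 and -0.31. Of 9 other HNRNPA1L2 probes, 8 read between -1.18 and -0.70 and 1 read 0.09. The authors' deposited table gives 78.7% of control for HSPA1A, 79.8% for UBE2Z, and 105% and 58.2% for 2 accessions of HNRNPA1L2. Its ratios, made from the same arrays, correlated with those here with r = 0.769 across 13086 genes. Among the target and the largest changes, 22 of 23 genes with a value there had the same sign.

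The largest rise was that of PDIA4, a protein disulfide isomerase of the endoplasmic reticulum, at 1.48 ± 0.17 on the log2 scale (SD, n = 3; limma, adjusted p = 6.66e-06). The oxytocin receptor gene OXTR rose by 1.17 ± 0.09, ARL6IP1 by 1.09 ± 0.09, and NEAT1, the long non-coding RNA on which paraspeckles assemble, by 1.06 ± 0.35. STT3A, a catalytic subunit of oligosaccharyltransferase, rose by 1.04 ± 0.08. SNRNP40 rose by 1.00 ± 0.03, ARGLU1 by 0.97 ± 0.10 and CALB2, which encodes calretinin, by 0.96 ± 0.09. The second NEAT1 probe read 0.99 and the second OXTR probe 0.37. For 3 further genes the probes disagreed. ZNF644 read 1.43 ± 0.49 on the probe used and between -0.29 and 0.23 on the others, and the authors' deposited table gives 80.9% of control for 2 of its accessions and 113% for 1. HS2ST1 read 0.96 ± 0.23 on the probe used and between -0.18 and -0.04 on the others, and with the mean of all its probes it was no longer past the threshold (0.15, limma, adjusted p = 0.071). HNRNPA3 read 1.59, 0.62 and 0.72 on the arrays, where the probe was saturated on 1 array, so its mean of 0.98 ± 0.53 is not exact. Its 7 other probes read between -0.86 and 1.08.

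**Figure D1:**
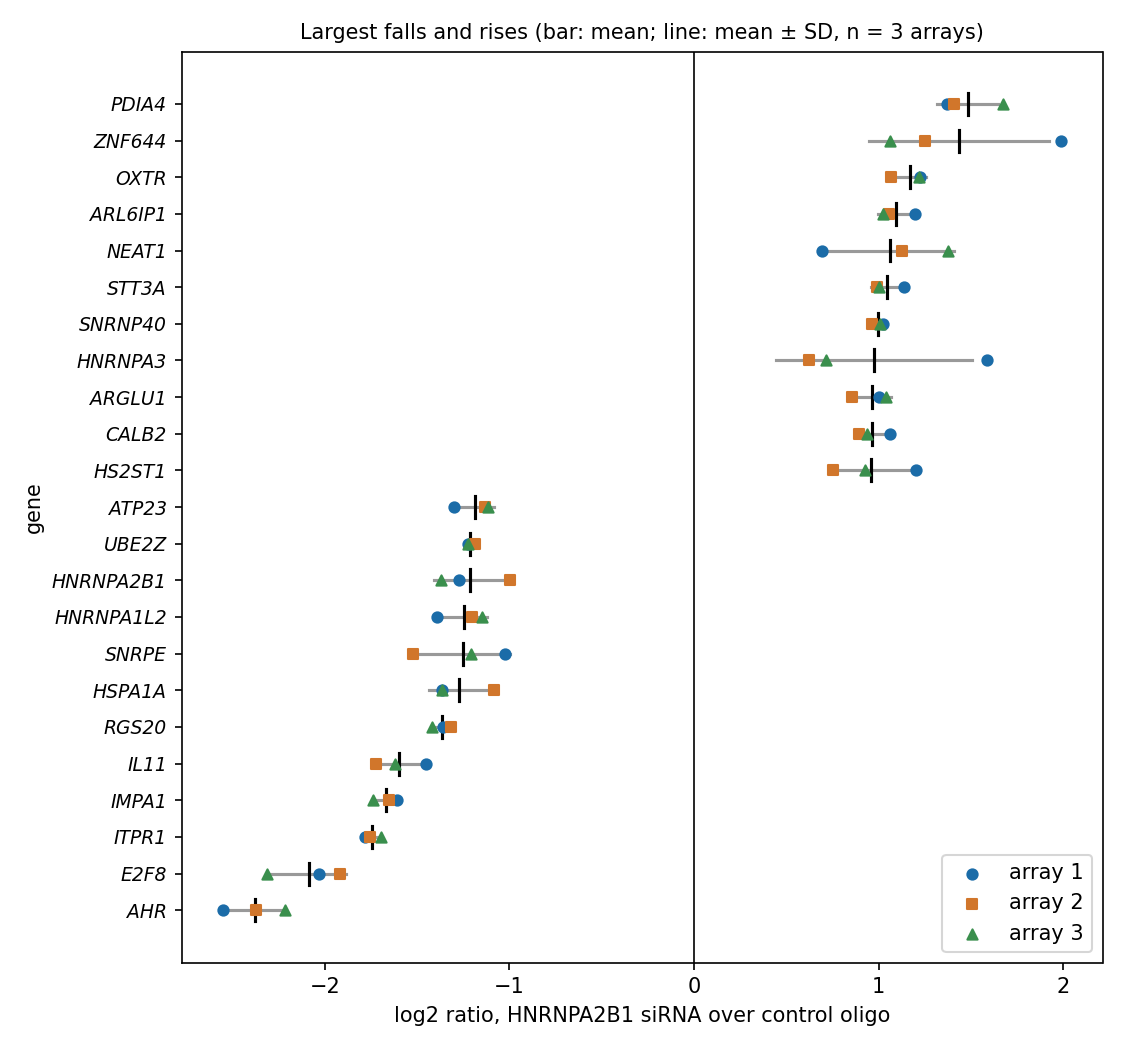
Log2 ratio of HNRNPA2B1 siRNA over control oligo (x axis) for the genes with the largest falls and rises (y axis). Symbols are the 3 arrays, the black bar is their mean and the grey line the mean ± SD. AHR has the lowest mean (-2.38) and PDIA4 the highest (1.48), and array 1 stands apart for ZNF644 and HNRNPA3.

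Over all 22335 genes tested, 9314 passed the threshold, of which 4763 were lower and 4551 higher in the siRNA channel (limma, Benjamini-Hochberg adjusted p under 0.05). Most of these differences were small: the median size was 0.31 on the log2 scale, 1559 genes reached 0.5 and 52 reached 1, with 39 lower and 13 higher. With processed signals 1245 lower and 1527 higher genes reached 0.5, and with median centring 4556 lower and 129 higher. Without array 2, 5767 genes passed. The split depends on the scaling: with median centring in place of loess, the median of all genes tested moved to -0.18, and 11064 genes were lower and 2940 higher, or 21% higher in place of 48.9%. Counts of list members after median centring, given below, are to be read against these counts out of 22335. Those with loess are to be read against the 41.7% of all genes tested that passed with loess, 4763 lower and 4551 higher. The log2 ratios of the arrays correlated across genes with Pearson r of 0.828 (arrays 1 and 2), 0.743 (arrays 1 and 3) and 0.824 (arrays 2 and 3). Genes are not independent replicates, and a fixed dye effect would also make arrays alike.

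**Figure D2:**
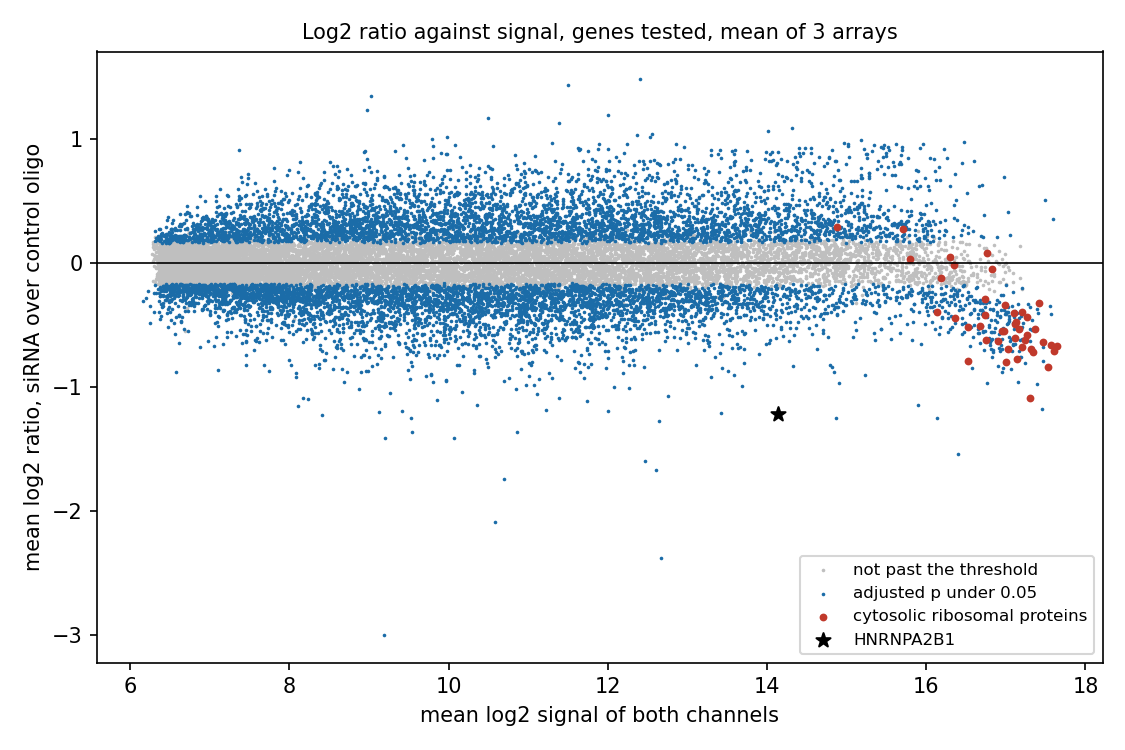
Mean log2 ratio of siRNA over control oligo (y axis) against mean log2 signal of both channels (x axis) for the 22335 genes tested. Blue points passed the threshold (9314 genes), grey points did not, red points are cytosolic ribosomal protein genes and the star is HNRNPA2B1. Above a log2 signal of about 16.5 the ratios of ribosomal and of other genes bend below 0.

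Genes of cholesterol synthesis and uptake rose together under every scaling but median centring, where the mean of the list was -0.13 (camera adjusted p = 0.556). Of 24 measured, 15 rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 ratio of 0.25 and camera adjusted p = 3.14e-07, and adjusted p = 0.559 with an estimated correlation; after median centring 3 were higher and 12 lower. MSMO1 rose by 0.69 ± 0.12 and MVK, mevalonate kinase, by 0.67 ± 0.08 (SD, n = 3), and EBP read 0.62 ± 0.02. After median centring MVK (0.12) and EBP (-0.04) did not pass. Under that scaling 11064 of all 22335 genes tested were lower and 2940 higher. Their median was -0.18, against -0.14 for the list.

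The lists of interferon response genes and of NF-kappaB cytokines were lower as groups. The second list also holds genes that encode no cytokine, among them NFKB1, NFKB2, NFKBIA, RELB, ICAM1, SOD2, IER3 and TRAF1. Of 38 interferon response genes, 23 fell and 1 rose (24 and 2 adjusted over the list alone), with a median of -0.29 and camera adjusted p = 2.08e-05, and adjusted p = 0.559 with an estimated correlation. After median centring 1 was higher and 31 lower, with a median of -0.54. IRF1, a transcription factor of this response, fell by 0.88 ± 0.02, XAF1 by 0.71 ± 0.07, SAMD9L by 0.70 ± 0.19 and HERC6 by 0.68 ± 0.06 (SD, n = 3). MX1 (-0.62) and ISG15 (-0.44) were also among the 23 that fell, and BST2 was the 1 that rose (0.33). IFIT1 (-0.13), IFIT2 (0.03), IFIT3 (-0.03), OAS1 (0.03) and STAT2 (0.004) were among those that did not pass. Of 26 measured genes of the NF-kappaB list, 14 fell and 1, RELB, rose (14 and 1 adjusted over the list alone). The median was -0.25, with camera adjusted p = 2.08e-05, and adjusted p = 0.559 with an estimated correlation. Among its cytokine genes, TNF (-0.04), CXCL8 (0.19), CCL2, CXCL2, CXCL3 and CXCL5 did not pass, while IL1A, IL1B, IL6, CSF3, CXCL1 and LIF fell. CSF3 was well above background in the siRNA channel on 0 of 3 arrays, so its size is not exact. IL6 read -0.94, -0.49 and -0.06 on the arrays. After median centring 0 genes of the NF-kappaB list were higher and 23 lower, with a median of -0.67. Beside IL11, IER3 fell by 1.14 ± 0.30, CSF2, which encodes GM-CSF, by 0.95 ± 0.04, and TRAF1 by 0.92 ± 0.17. The other probes of these genes had medians of -0.22 for the interferon list (15 probes) and -0.25 for the NF-kappaB list (4 probes).

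Cytosolic ribosomal protein genes also had lower ratios, as had other genes of the same brightness. Of 43 measured, 35 fell and 2 rose (35 and 2 adjusted over the list alone), with a median of -0.53 and camera adjusted p = 8.21e-13, and adjusted p = 0.559 with an estimated correlation. The median was -0.25 with the scanner software's processed signals, where 17 were lower and 2 higher, -0.35 with the mean of all probes of a gene, and -1.32 after median centring. Without array 2, 26 were lower, and without array 3, 23. RPL7A fell by 1.09 ± 0.19, RPL35 by 0.84 ± 0.05 and RPS7 by 0.80 ± 0.12 (SD, n = 3), while the highest of their other probes read -0.05, 0.19 and -0.04, and RPS7 did not pass with processed signals (-0.28). Random lists of other genes matched on signal had a median of -0.36. In intervals of log2 signal that begin at 16.5, 16.75, 17 and 17.25, other genes had medians of -0.22, -0.39, -0.47 and -0.53, and ribosomal genes -0.51, -0.55, -0.57 and -0.61. From 14 to 16 and from 16.25 to 16.5 the ribosomal medians lay above (0.28 and -0.02, 3 genes each, against 0.07 and -0.14). From 16 to 16.25 and above 17.5 they lay below (-0.26 and -0.68, 2 and 4 genes, against -0.04 and -0.34). The 38 other, dimmer probes of the ribosomal genes had a median of -0.05, with 11 lower and 11 higher.

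Of 18 heat shock protein genes, 9 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.17 and camera adjusted p = 0.00622, and adjusted p = 0.559 with an estimated correlation. With the mean of all probes of a gene the list no longer passed (adjusted p = 0.0534), and after median centring its median was -0.75, with 16 lower. Without array 2 only 4 were lower, and with processed signals 5. HSPD1 fell by 0.62 ± 0.12 (SD, n = 2; second probe 0.005) and HSPA8 by 0.48 ± 0.13 (n = 3; -0.17 and not past the threshold with processed signals), both at signals where most genes read below 0, and the list's 14 other probes had a median of -0.04. The estimated correlation, with which none of the 5 list calls held, leaves few residual degrees of freedom. In simulated data with 1 list truly shifted, camera with it gave adjusted p = 0.632. The estimates were 0.25 for NF-kappaB, 0.21 for ribosomal, 0.043 for heat shock, 0.029 for interferon and 0.023 for cholesterol genes. All lay above the preset 0.01. Whether the calls were lost for want of power or because the preset is too low for these lists cannot be told apart. Of 10000 random lists matched on signal, 4.16% had a lower median than the heat shock list. The share was 0% for the interferon and NF-kappaB lists and 99.95% for cholesterol synthesis. Genes of a list are not independent, so these shares are not p-values.

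**Figure D3:**
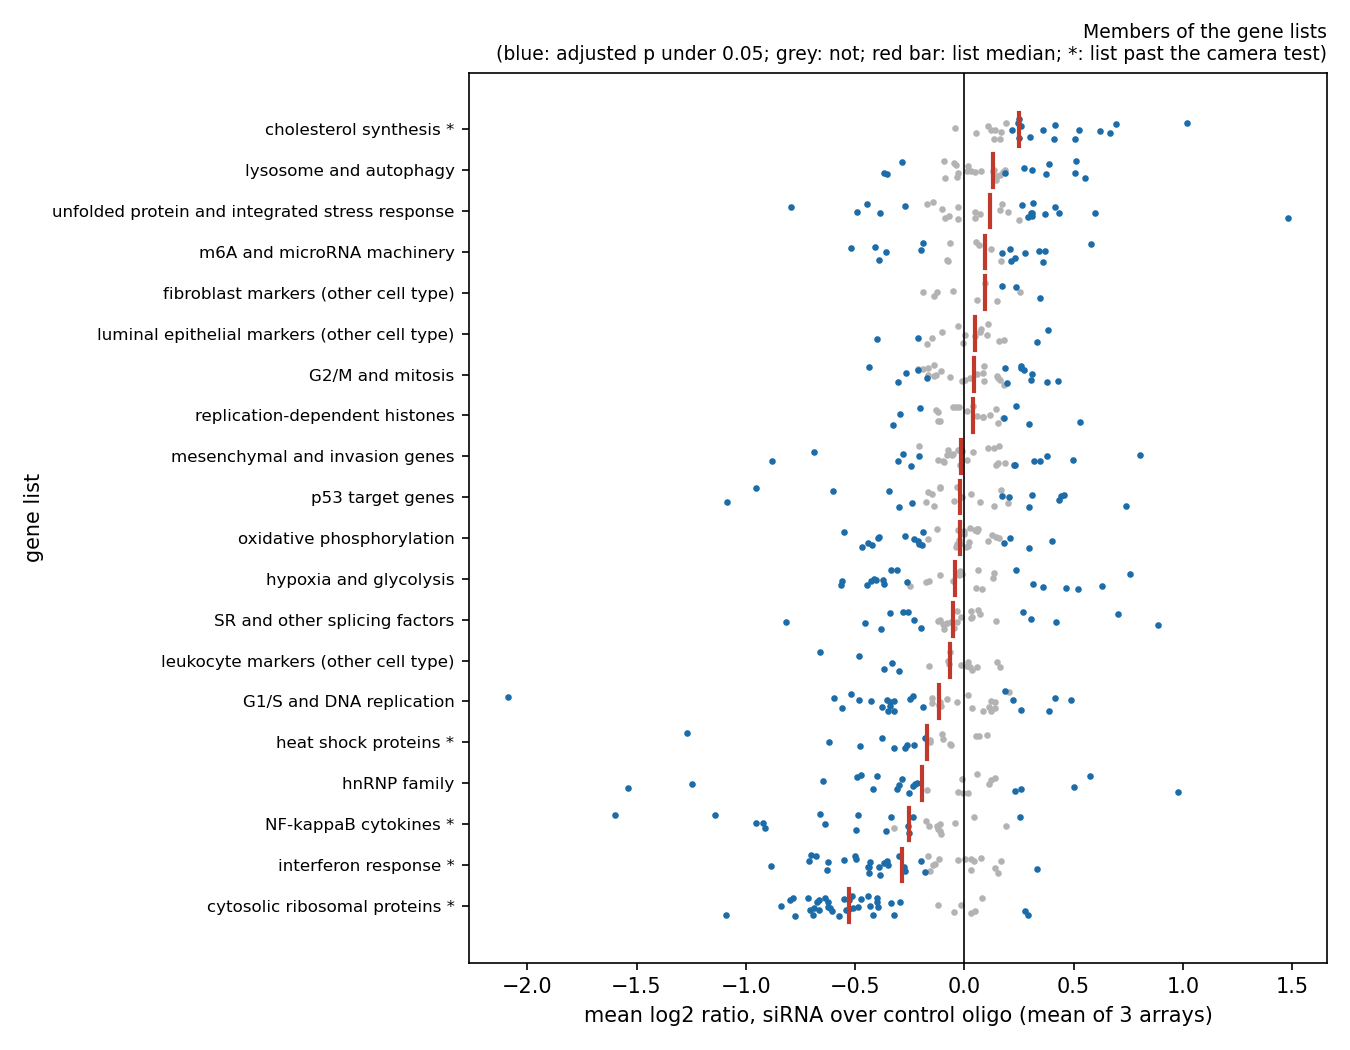
Mean log2 ratio of siRNA over control oligo (x axis) of each measured member of the 20 gene lists (y axis). Blue points passed the threshold, grey points did not, red bars are list medians and asterisks mark the 5 lists past the camera test. The medians run from -0.53 for ribosomal proteins to 0.25 for cholesterol synthesis, whose mean is -0.13 after median centring, where the median of all genes is -0.18.

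The hnRNP family, to which the target belongs, changed in both directions. Of 28 other members, 14 fell and 5 rose (15 and 5 adjusted over the list alone), with a median of -0.19 and camera adjusted p = 0.0849. The list passed without array 1 (adjusted p = 0.0463), with no filter on dim probes (0.0360), by fry (0.0118) and after median centring (1.94e-05, with 1 higher and 24 lower). Of 10000 random lists matched on signal, 0.03% had a lower median. By fry the lists of splicing factors (adjusted p = 0.0118), unfolded protein response (0.0317) and leukocyte markers (0.00281) passed too. Fry therefore did not single out the hnRNP family. Without array 2, 3 were higher and 9 lower, and the family's 46 other probes had a median of -0.03. HNRNPA1 fell by 1.54 ± 0.05 (SD, n = 2, with the spot of array 1 left out as an outlier; limma, adjusted p = 1.65e-05), and its 3 other probes read -1.23, -0.93 and -0.82. HNRNPR fell by 0.65 ± 0.02. Of 30 SR proteins and other splicing factors, 5 rose and 8 fell (5 and 8 adjusted over the list alone; median -0.05, camera adjusted p = 0.558). After median centring 3 were higher and 25 lower (median -0.52, adjusted p = 0.00280), and with the mean of all probes the list mean was 5.01e-05. TRA2A rose by 0.89 ± 0.18 (second probe 0.10) and RBM25 by 0.70 ± 0.11, while SRSF2 fell by 0.82 ± 0.10 and RBM39 by 0.45 ± 0.06. Of 22 genes of m6A and microRNA machinery, 9 rose and 6 fell (10 and 6 adjusted over the list alone; median 0.10, camera adjusted p = 0.497; mean -0.29, 1 higher and 13 lower after median centring; 5 higher and 4 lower without array 2). DGCR8, a partner of DROSHA in microRNA processing, rose by 0.58 ± 0.13 (second probe -0.12), and the m6A readers YTHDF3 and YTHDF2 fell by 0.52 ± 0.09 and 0.39 ± 0.05 (second YTHDF2 probe 0.06).

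Cell cycle lists did not pass in the fit of all 3 arrays with loess, and 2 of them passed as lower after median centring. Of 38 G1/S and DNA replication genes, 16 fell and 6 rose (16 and 7 adjusted over the list alone; median -0.11, camera adjusted p = 0.136). Beside E2F8, MCM3 fell by 0.60 ± 0.22 and SLBP by 0.56 ± 0.11. The list passed without array 1 (adjusted p = 0.0254), without array 2 (adjusted p = 0.0138) and after median centring (adjusted p = 7.86e-06; 0 higher, 35 lower), and without array 2 only 2 were higher. Of 34 G2/M genes, 9 rose and 5 fell (9 and 6 adjusted over the list alone; median 0.04, camera adjusted p = 0.558; mean -0.45, 0 higher, 29 lower and adjusted p = 0.000433 after median centring; 4 higher and 3 lower without array 2, and 5 and 2 with processed signals). PTTG1 fell by 0.44 ± 0.05, at a signal where the median of other genes was -0.39, and CDK1 read 0.43 ± 0.10, or -0.11 after median centring. Of 23 replication-dependent histone genes, 4 rose and 3 fell (2 and 2 adjusted over the list alone; median 0.04, camera adjusted p = 0.558; mean -0.33, 0 higher and 18 lower after median centring; median -0.06, 2 higher and 4 lower without array 1; median 0.12, 3 higher and 0 lower without array 2). Histone genes are near-identical copies, so their probes may read several of them.

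Stress and metabolic lists held changes in both directions with loess, where 41.7% of all genes tested passed, and mostly lower members after median centring. Of all 22335 genes tested, 11064 were lower and 2940 higher under that scaling, so the counts are to be read against that share. Of 28 p53 target genes, 8 rose and 6 fell (8 and 7 adjusted over the list alone; median -0.02, camera adjusted p = 0.960; 1 higher and 15 lower after median centring, and 4 and 5 without array 2). TRIM22 fell by 1.09 ± 0.11 and FAS by 0.95 ± 0.14, while the apoptosis gene BBC3 rose by 0.74 ± 0.23 (other probes 0.24 and 0.01), but read 0.03 and did not pass after median centring. Of 30 genes of the unfolded protein and integrated stress responses, 11 rose and 5 fell (13 and 5 adjusted over the list alone; median 0.12, camera adjusted p = 0.172; mean -0.36, 3 higher, 22 lower and adjusted p = 0.0495 after median centring; 7 higher and 4 lower without array 2). Beside PDIA4, PHGDH rose by 0.60 ± 0.06, while SLC7A11 fell by 0.79 ± 0.18. Of 32 hypoxia and glycolysis genes, 7 rose and 11 fell (7 and 12 adjusted over the list alone; median -0.04, camera adjusted p = 0.486; 1 higher, 25 lower and adjusted p = 0.000875 after median centring; 5 higher and 6 lower with processed signals). PFKL rose by 0.76 ± 0.11 (SD, n = 2; second probe 0.15) and PFKP fell by 0.57 ± 0.11. Of 39 oxidative phosphorylation genes, 4 rose and 12 fell (4 and 12 adjusted over the list alone; median -0.02, camera adjusted p = 0.423; median -0.64, 0 higher, 37 lower and adjusted p = 2.62e-09 after median centring; median 0.01, 3 higher and 6 lower without array 2), and COX7C fell by 0.55 ± 0.01, at a signal where the median of other genes was -0.22. Of 29 lysosome and autophagy genes, 8 rose and 3 fell (8 and 3 adjusted over the list alone; median 0.13, camera adjusted p = 0.0791; mean -0.29, 1 higher and 19 lower after median centring), and PSAP rose by 0.55 ± 0.18, but read 0.12 and did not pass after median centring. The list passed without array 1 (adjusted p = 0.0151) and with no filter on dim probes (adjusted p = 0.0360), while its 15 other probes had a median of -0.08.

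Of 32 mesenchymal and invasion genes, 7 rose and 6 fell (7 and 6 adjusted over the list alone). The median was -0.01 and the mean 0.01 (camera adjusted p = 0.558), and after median centring the mean was -0.34, with 4 higher and 21 lower. Under that scaling 11064 of all 22335 genes tested were lower and 2940 higher. Without array 2, 5 were higher and 3 lower. VIM, which encodes vimentin, fell by 0.88 ± 0.39, at a signal where the median of other genes was -0.39, and the collagenase gene MMP1 by 0.69 ± 0.14, while THBS1 rose by 0.80 ± 0.05 and the integrin gene ITGA5 by 0.50 ± 0.06. Among markers of other cell types, 2 of 17 luminal epithelial genes rose and 2 fell (2 and 0 adjusted over the list alone; median 0.05, camera adjusted p = 0.558; mean -0.21, 1 higher and 6 lower after median centring; 2 higher and 0 lower without array 2, and 2 and 1 without array 3). Of 17 leukocyte genes, 5 fell and 0 rose (5 and 0 adjusted over the list alone; median -0.06, camera adjusted p = 0.217; 4 higher and 9 lower after median centring), and HLA-DRA fell by 0.66 ± 0.09 and CD74 by 0.48 ± 0.08. Of 11 fibroblast genes, 3 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.10, camera adjusted p = 0.435; mean -0.06, 2 higher and 4 lower after median centring; 1 higher and 1 lower without array 2).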

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

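All tests of explanations here were chosen or revised after the result was seen, except those of agreement between probes, of the sign patterns and of other probes of the ribosomal and HNRNPA1 patterns, and that of base composition for the ribosomal genes, which rests on a correction added after seeing the data but had its bounds set before its result.

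Some control spots carried signal outside the gene measurements. The control probe (+)E1A_r60_a22 was well above background in Cy3 in 64 of 96 spot readings (66.7%), ETG05_66023 in 28 of 30 (93.3%), and 8 of 10 probes named AT_ssH on every spot, against 6 of 459 readings (1.31%) of negative controls.

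The 9314 genes past the threshold are many for 3 arrays. A dye effect tied to base composition as the cause of most calls is argued against, since 91.5% of calls kept their sign and passed after composition was regressed out. A dye effect specific to each probe cannot be told apart from a change in the cells, because no dyes were swapped. Separate probes of 5113 genes correlated with r = 0.349 across genes (highest of 100 shuffles 0.043), which lies between the bounds set for either reading. Where the first probe passed (2517 of these genes), the second passed with the same sign in 905 and the opposite sign in 277. Over the arrays only 4 sign patterns exist, too few for a share under 0.05: the real one, 1 of the 4, gave 9314 genes and the highest other 0.

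The greater part of the lower ribosomal ratios may come from a bend at the bright end of the scale: random lists matched on signal reached 67.7% of the ribosomal median. Whether the bend accounts for the whole cannot be told apart from a further fall. Only 0.05% of matched lists were as low, but few other genes are as bright, and 28 of 43 ribosomal genes lay below the median of their 5 or 10 nearest genes (exact sign test over genes, which are not independent, p = 0.0660), 29 of their 20 nearest (p = 0.0315) and 31 of their 40 nearest (p = 0.00540). A property of the probe chosen may also account for it, since the other, dimmer probes had a median of -0.047. The chosen probe is by rule the brightest, so that median cannot tell a property of the probe apart from the bend. Base composition is argued against by a median of -0.54 after its removal. No change of ribosomal mRNA in the cells can be claimed from these data.

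HNRNPA1 fell on the chosen probe by more than the target. A property of that single probe is argued against, since the highest of the 3 other probes still read -0.82, although 2 of these 3 fell by less than HNRNPA2B1. Whether HNRNPA1 probes also bind HNRNPA2B1 transcripts cannot be told apart from a fall of HNRNPA1 itself. With outlier spots kept, the HNRNPA1 probe fell further than that of HNRNPA2B1 on 3 of 3 arrays, by -0.41, -0.57 and -0.12. The bound set was 2 combined standard errors (0.22), which the last did not reach. Those are errors of means over arrays, for HNRNPA1 without the outlier spot, so the bound does not measure the spread on a single array. A fall of HNRNPA1 upon knock-down, or siRNA acting on both mRNAs, stays open and was not tested.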

How the results depend on the processing

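The base composition alternative was chosen after seeing the data. HNRNPA2B1 kept its direction and passed under every setting run, from -1.13 to -1.72. Genes past the threshold numbered 14004 with median centring, 1559 with a minimum size of 0.5, and 5767 to 8758 with 1 array left out. Without the array as a replicate block, 7971 passed. Lists past the threshold numbered 11 with median centring, 0 with an estimated correlation, 9 by fry and 5 to 8 with 1 array left out. The agreement between sets, as mean correlation between arrays 0.798, was 0.743 with processed signals, 0.870 with median centring and 0.743 to 0.828 with 1 array left out. Aquantile leaves the ratio of each spot as it is by construction, and 9311 genes passed with it. The authors' table holds no values per array, so it was not run as a test.

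Of the named genes, 1386 values under other settings kept direction and side of the threshold and 44 no longer passed, among them the 8 that turned sign. ALDOA, at 0.63 with loess, turned to -0.21 with processed signals, and its second probe read -0.24 with loess. The second probes of H2AC11 (0.07) and FBLN1 (0.03) did not pass. With median centring CDK1 turned to -0.11, AURKB to -0.014, H2AC11 to -0.12, EBP to -0.044, CTSA to -0.084, FBN1 to -0.080 and FBLN1 to -0.071. Of list means, 274 kept both, 13 newly passed, 2 no longer did and 14 turned sign, of which 2 newly passed and 1 no longer did. With median centring the means were -0.29 for m6A and microRNA machinery, -0.45 for G2/M, -0.33 for histones, -0.36 for the unfolded protein list, -0.13 for cholesterol synthesis, -0.34 for mesenchymal genes, -0.29 for lysosome, -0.21 for luminal and -0.058 for fibroblast markers. With the mean of all probes they were 5.01e-05 for splicing factors and -0.00083 for histones. With 1 array left out, histones ranged from -0.052 to 0.12, mesenchymal genes from -0.031 to 0.060 and luminal markers from -0.0013 to 0.048. Median centring leaves the trend of ratio with signal in place, and the median of all genes tested was -0.18 under it. For the other changes the cause was not tested.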

Other observations

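The tests here were chosen or revised after the data were seen, and both lists were assembled for them.

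Genes of protein translocation and N-glycosylation in the endoplasmic reticulum, drawn up after the rises of PDIA4 and STT3A were seen and without these 2 genes, had a median log2 ratio of 0.15, but of -0.41 after median centring, where the median of all genes was -0.18 and 0 of these genes were higher and 34 lower. Of 40 measured, 16 rose and 8 fell (10 and 7 without array 2), and MOGS (0.46), SRPRA (0.46) and DDOST (0.44) led the rises, none of which held after median centring. The median lay above those of 99.6% of 10000 random lists matched on signal, which is consistent with the hypothesis that the group rose relative to genes of like signal, and 27 other probes of these genes had a median of 0.15.

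A second hypothesis was that mRNAs outside the ribosome with a terminal oligopyrimidine tract, which share translational control with ribosomal protein mRNAs, fell too. The 18 genes had a median of -0.083 (0.092 with the scanner software's processed signals), against -0.10 for matched random lists, and 5 rose and 6 fell. After median centring the median was -0.83, with 1 gene higher and 14 lower. EEF1A1 and HNRNPA1 belong to this class, were first left out and were added after their values were seen: the 20 genes then had a median of -0.094 (0.074 with processed signals), and 5 rose and 8 fell. With loess, 56.4% of 10000 random lists matched on signal had a lower median than the 18 genes, and 60.1% than the 20. No shared fall beyond that of genes of like signal was therefore seen with loess. Since members went both ways and the median depends on the scaling, a small shared fall cannot be told apart from none.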
